A study of Homo sapiens with 10 samples.

How the data were processed

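RNA-seq was measured in U2OS cells, a human osteosarcoma line, in 3 groups of 2 libraries each: unheated control cells, heat-shocked control cells and heat-shocked cells in which YTHDC1, a nuclear reader of m6A (N6-methyladenosine, a modified base in messenger RNA), was knocked down. Per the labels, total RNA was extracted with TRIzol and libraries for the DNBSEQ-T7 were made with the VAHTS Universal V8 kit. The sample titles call the reagents sh, whereas the descriptions and the design text call them si, so whether a short hairpin or a small interfering RNA was used is uncertain and the word knockdown is used here. The temperature, length and recovery time of the heat shock are not given in the sources used here. The series also lists 4 methylated RNA immunoprecipitation samples from unmodified U2OS cells, which were not analysed here, so no value below measures m6A.

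The deposited values are whole-number read counts per gene, not normalized, with 63187 genes in 1 table. Per the submitters' processing notes, the tools named for the series were FastQC 0.11.8, Trim Galore 0.6.7, HISAT2 2.2.1, SAMtools 1.17, featureCounts 2.0.2, DESeq2 1.36.0, R 4.4.0 and MACS2, on GRCh38. Those notes give no order or role for them. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of near-identical copies, such as HSPA1A and HSPA1B, of overlapping genes and of antisense genes are therefore uncertain. The deposited gene length per the file headers was not used in any test.

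Ensembl identifiers were paired with symbols for 62666 genes, and the 521 without one held between 0.0602% and 0.0698% of the counts per library. Gene positions are RefSeq positions on GRCh38, patch 14, matched by symbol and chromosome. No genome sequence was used. Total counts ran from 13252370 to 15500743 per library. Simulated counts for the knockdown comparison were used to check the test. In them 200 genes were changed, a further list of genes was shifted together, and 16803 genes passed the filter. Among genes of at least 5 CPM the test recovered 52.8% of 1.25-fold, 82.5% of 1.5-fold and 100.0% of 2-fold changes. Among the 200 at any level it recovered 38% of 1.25-fold, 66% of 1.5-fold and 76% of 2-fold changes. Of 16584 unchanged genes that passed the filter it called 7. In the real knockdown comparison 54.5% of the tested genes were called, far more than were changed here, so these rates may not carry over. The simulated spread was the one fitted to these libraries, so variation between separate cultures was not checked.

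The main test was edgeR 4.0.16 (quasi-likelihood F test, robust, TMM scaling, genes kept by filterByExpr with a minimum count of 10) in R 4.3.3. All 6 libraries entered a single fit with 3 residual degrees of freedom, and 17290 genes were tested. Every adjusted p below without another name is edgeR's, after Benjamini-Hochberg adjustment over those genes, with 0.05 as the threshold. Fold changes are log2 with the standard error (SE). Levels are CPM, the count relative to the TMM-scaled library size, with the SD of the 2 libraries. The common biological coefficient of variation was 3.69%. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates differed by more than sampling noise, with a chi-square per gene of 1.55 in the unheated controls, 2.69 in the heat-shocked controls and 3.54 in the knockdown, so no library was counted as a copy of another.

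24 gene lists were fixed before the data were examined, and 23 had at least 3 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with p adjusted over the 23 lists. With the correlation estimated from the data, 3 of 12 calls held in heat shock, those of chaperones, HSF1 targets and p53 targets, and 0 of 8 held in the knockdown. There 5 of the lists had an unadjusted camera p under 0.05 with the estimated correlation. Lost calls need not reflect correlated members. The knockdown estimates were -0.02 for NF-kB targets, interferon-stimulated genes and HSF1 targets, and -0.03 for p53 targets and immediate early genes, all below 0.01. They were 0.16 for chaperones, 0.51 for G2/M genes and 0.53 for histones. A simulated list of genes shifted together went from an unadjusted camera p of 2.56e-16 to 0.00625 when the correlation was estimated. The lists were chaperones and co-chaperones, heat shock transcription factors with other HSF1 targets (HSF1 targets for short), 6 groups of DNA repair and damage signalling genes (end joining, homologous recombination, base excision, nucleotide excision, mismatch repair and damage signalling), p53 targets, the unfolded protein response, immediate early genes, m6A factors, splicing factors, ribosomal proteins, G1/S and G2/M genes, cholesterol synthesis, interferon-stimulated genes, NF-kB targets, matrix genes, mitochondrial messenger RNAs, histones, and epithelial and blood cell markers.

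The genes named were set by a rule fixed before the data were examined. For each main comparison the rule took the 8 largest rises and 8 largest falls among called protein-coding genes of at least 5 CPM whose libraries did not overlap between groups. It added every tested end joining gene, up to 4 members of each other list with the smallest adjusted p (or 2 given as values where none passed), YTHDC1, HSF1, and 5 genes per direction of opposite change, ranked by the sum of their 2 absolute log2 fold changes among genes of at least 5 CPM. Some of these were left out of the text, and a few genes are not reported here. Names outside the rule are marked as such.

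Alternatives were DESeq2 1.42.0 size factors and Wald test, upper-quartile scaling, library size alone, no filter and a stricter filter on low counts, limma voom, fits of only the groups compared, a replicate block, a fit without robust estimation, an adjusted p under 0.01, fry (a rotation test of lists) and the omission of each library in turn.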

Results

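Messenger RNA levels were compared in U2OS cells, a human osteosarcoma line, to ask how heat shock changed them and how YTHDC1 knockdown changed them in heat-shocked cells. The design centred on genes of non-homologous end joining, a pathway that rejoins broken DNA ends. Each of the 3 groups had 2 libraries. The libraries held 15500743 and 15077827 counts in unheated controls, 13252370 and 14286747 in heat-shocked controls, and 14419583 and 14497486 in heat-shocked knockdown cells. Mitochondrially encoded genes took between 5.09% and 6.12% of the counts per library.

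YTHDC1 (ENSG00000083896, chromosome 4, 68310387 to 68350090 on GRCh38), the targeted gene, was lower in both knockdown libraries. It stood at 213 and 225 CPM in unheated controls, 268 and 258 CPM in heat-shocked controls, and 121 and 118 CPM in the knockdown. The knockdown left 45.4% of the level of heat-shocked controls (log2 fold change -1.14 ± 0.05 SE, n = 2 per group, edgeR adjusted p = 2.66e-15). In control cells YTHDC1 rose with heat (log2 fold change 0.27 ± 0.05, adjusted p = 4.44e-05). HSF1, the main transcription factor of the heat shock response, was at 152 ± 3.28 CPM before and 147 ± 0.805 CPM after heat shock (adjusted p = 0.396) and rose to 178 ± 4.5 CPM in the knockdown (log2 fold change 0.27 ± 0.05, adjusted p = 2.92e-05). With library size alone HSF1 was called lower in heat shock (log2 fold change -0.12, adjusted p = 0.0364).

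**Figure D1:**
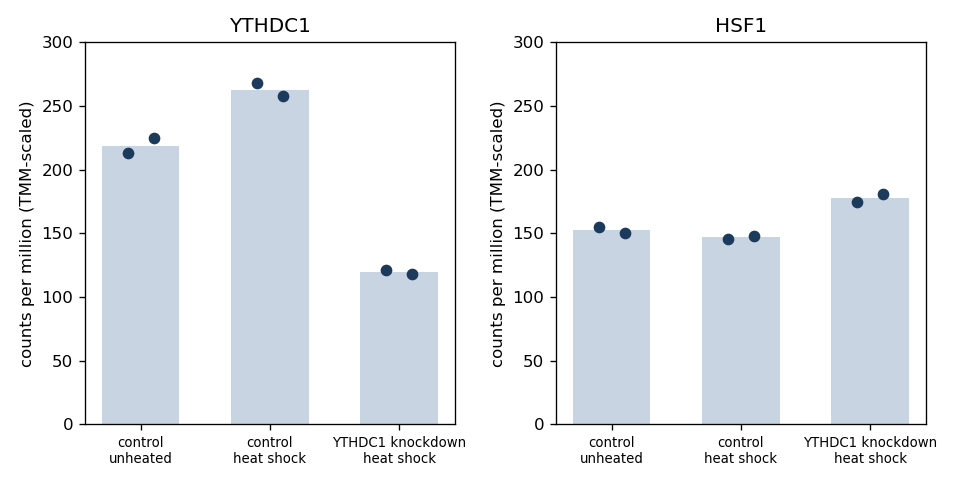
Levels (y axis, CPM) of YTHDC1 and HSF1 in each library (points) with the mean of the 2 libraries (bars), for unheated controls, heat-shocked controls and heat-shocked knockdown cells. The knockdown libraries held 121 and 118 CPM of YTHDC1 against 268 and 258 CPM in heat-shocked controls.

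Among protein-coding genes of at least 5 CPM on average, the 3 largest rises with heat shock in control cells were of HSP70 chaperone genes, which help proteins fold. HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526894), a stress-induced HSP70, rose from 4.74 ± 0.0733 to 1498 ± 53.4 CPM (SD, n = 2), which was 315-fold (log2 fold change 8.30 ± 0.08 SE, adjusted p = 1.74e-28). HSPA1A rose 91-fold, from 51 ± 2.08 to 4640 ± 227 CPM, and its near-identical neighbour HSPA1B rose 101-fold, though reads between those copies could not be assigned with certainty. The HSP40 co-chaperones DNAJA4 and DNAJB1 rose 59.1-fold and 16.2-fold. Of 43 chaperone and co-chaperone genes tested, 38 rose and 2 fell (38 and 2 adjusted over the list alone), with a median log2 fold change of 1.72 (camera adjusted p = 1.74e-231, and adjusted p = 0.00906 with an estimated correlation).

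Other known HSF1 targets rose as well. ZFAND2A, a proteasome-associated zinc finger protein, rose 24-fold (log2 fold change 4.58 ± 0.07), DEDD2 rose 9.51-fold, JMJD6 5.25-fold and SLC5A3, a myo-inositol transporter, 3.34-fold. Their list also held the heat shock transcription factors, HSF1 among them. In it 12 of 19 genes rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 2.78e-46, and adjusted p = 0.00906 with an estimated correlation). Genes near silence before heating also appeared among the largest rises above that level. PNLDC1, a poly(A)-specific ribonuclease whose gene starts 1026 bp beyond the expressed gene MRPL18, went from 0.255 ± 0.0933 to 23.6 ± 2.33 CPM. TNFSF14, a cytokine of the TNF family, went from 0.224 ± 0.138 to 17.1 ± 0.0395 CPM, and PLPPR5 from 0.414 ± 0.0504 to 17.6 ± 0.593 CPM. The largest falls above it were of HPS6 (6.05-fold), FJX1 (5.52-fold), IFIT1 (5.24-fold), CAVIN2 (4.63-fold), FOXS1, LFNG, BMF and BBC3, with log2 fold changes between -2.60 and -2.06.

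Targets of p53 fell together in heat-shocked controls. Of 26 tested, 20 fell and 3 rose (21 and 3 adjusted over the list alone), with a median log2 fold change of -0.36 (camera adjusted p = 1.20e-11, and adjusted p = 0.0323 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, fell from 442 ± 8.02 to 195 ± 14.6 CPM, and the log2 fold change was -2.03 for BTG2, -1.78 for PLK2 and -2.06 for BBC3, a pro-apoptotic BCL2 family gene. Of 27 G2/M genes, 21 fell and 1 rose (21 and 1 adjusted over the list alone), with KIF11 at -0.79 and CENPF at -0.58 (camera adjusted p = 1.95e-06). The G2/M list had adjusted p = 0.463 with an estimated correlation. Of 25 G1/S genes, 18 fell and 3 rose (18 and 3 adjusted over the list alone), among them PCNA, the replication clamp, at -1.34 and MCM3 at -0.66 (camera adjusted p = 0.00205, but adjusted p = 0.436 with an estimated correlation). SLBP, which binds histone messenger RNA, rose (log2 fold change 0.69).

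End joining genes moved in both directions in heat shock. Of 22 tested, 5 rose, 6 fell and 11 did not pass (5 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.913). NHEJ1 (ENSG00000187736, chromosome 2, 219069357 to 219160815), which encodes the ligation factor XLF, rose from 8.05 ± 0.3 to 15.4 ± 0.14 CPM (log2 fold change 0.94 ± 0.13, adjusted p = 2.98e-06). APTX, which removes adenylate from broken ends, rose by 0.56, DCLRE1C, the nuclease Artemis, by 0.26, RNF168 by 0.23 and PRKDC, the catalytic subunit of DNA-PK, by 0.11. SHLD2 and POLM fell by 0.68 each, PAXX by 0.51, SETMAR by 0.49 and RIF1 by 0.33. XRCC6 and XRCC5, the Ku subunits, were at log2 fold changes of 0.02 and 0.05 (adjusted p = 0.786 and 0.411), LIG4 at 0.06 (0.576), XRCC4 at 0.03 (0.906) and TP53BP1 at -0.05 (0.485). Calls of the small changes depended on the settings and on single libraries. With the DESeq2 Wald test the calls of RNF168 and DCLRE1C were lost (adjusted p = 0.097 and 0.0616). With library size alone those of RNF168 and PRKDC were lost (adjusted p = 0.0906 and 0.417) and POLL was called lower (-0.25, adjusted p = 0.0296), and with no filter the call of PRKDC was lost (0.0548). Without unheated replicate 1 the calls of PRKDC and DCLRE1C were lost (adjusted p = 0.168 and 0.141). Without unheated replicate 2 those of RNF168 and PRKDC were lost (adjusted p = 0.205 and 0.235) and SHLD3 was called (0.046). Without heat-shocked control replicate 1 the calls of RNF168 and PRKDC were lost (adjusted p = 0.116 and 0.186). Without heat-shocked control replicate 2 those of PRKDC and DCLRE1C were lost (adjusted p = 0.0686 and 0.0517).

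In each of the other repair lists more called genes fell than rose. In base excision repair 12 of 21 genes fell and 1 rose (12 and 1 adjusted over the list alone), led by FEN1, the flap endonuclease, at -1.16 (camera adjusted p = 0.00846, but adjusted p = 0.243 with an estimated correlation). In mismatch repair 5 of 8 fell and 1 rose (5 and 1 adjusted over the list alone), including PCNA and MSH6 at -0.53 (camera adjusted p = 0.00377, but adjusted p = 0.212 with an estimated correlation). In damage signalling 11 of 18 fell and 2 rose (11 and 2 adjusted over the list alone), with ETAA1 at -1.06 and HUS1 at 0.61 (camera adjusted p = 0.0343). That call was lost with adjusted p = 0.53 with an estimated correlation, and at the preset value without heat-shocked control replicate 2 (0.0597). Homologous recombination had 11 of 30 genes lower and 2 higher (11 and 2 adjusted over the list alone; camera adjusted p = 0.31), with BARD1 at -0.88 and EXO1 at 0.57. Nucleotide excision repair had 5 of 22 lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.31), with XPC, a damage sensor, at -1.12.

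3 further lists were called higher and 1 lower in heat shock by camera at the preset correlation, but not at the estimated one. In the unfolded protein response 16 of 24 genes rose and 2 fell (16 and 2 adjusted over the list alone), with CHAC1 up 6.49-fold and PPP1R15A up 2.65-fold (camera adjusted p = 1.80e-04, but adjusted p = 0.354 with an estimated correlation). Of 26 immediate early genes 15 rose and 6 fell (16 and 7 adjusted over the list alone), with FOS up 11.9-fold, EGR1 up 2.47-fold and IER3 at -1.85 (camera adjusted p = 0.00205, but adjusted p = 0.181 with an estimated correlation). Of 75 ribosomal protein genes 40 rose and 1 fell (47 and 1 adjusted over the list alone) by a small amount, with a median of 0.14 and RPL37A at 0.33 (camera adjusted p = 0.00348, but adjusted p = 0.436 with an estimated correlation). Interferon-stimulated genes went lower, 16 of 26 against 3 higher (16 and 3 adjusted over the list alone), with IFIT2 at -2.19 and IFIT3 at -1.58, while STAT2 rose by 0.81 (camera adjusted p = 0.0162, but adjusted p = 0.225 with an estimated correlation).

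The remaining lists were not called by camera in heat shock. NF-kB targets had 4 of 15 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.787), with PTGS2, the inducible cyclooxygenase, at 2.79 and LIF at -0.73. Splicing factors had 12 of 28 higher and 11 lower (12 and 11 adjusted over the list alone; adjusted p = 0.39), with the kinase CLK1 at 1.60 and SRSF2 at -0.78. Of 22 m6A factors 9 were higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.787), and the 2 that fell were RBM15B (2-fold lower) and YTHDF2 at -0.75. Cholesterol synthesis had 6 of 22 higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.333), with HSD17B7 at 1.96, and its median of -0.02 differed in sign from its mean of 0.13. Matrix genes had 2 of 26 higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.117), with CCN2 at -1.42. Mitochondrial messenger RNAs had 3 of 13 lower (3 adjusted over the list alone; adjusted p = 0.358), with MT-CO3 at -0.44. Of 12 histone genes 0 passed by edgeR, as by DESeq2 and limma voom, and 2 had an unadjusted edgeR p under 0.05 (0 adjusted over the list alone; adjusted p = 0.787). H2AC6 was called in the fit of only the 2 groups (adjusted p = 0.0128), with no filter (0.0493) and without unheated replicate 2 (0.0309), heat-shocked control replicate 2 (0.0482), or knockdown replicate 1 (0.0249) or replicate 2 (0.0218). H2BC4 was called with library size alone (adjusted p = 0.024) and without heat-shocked control replicate 2 (0.0476), or knockdown replicate 1 (0.0432) or replicate 2 (0.0444). Epithelial markers had CLDN4 higher (0.58) and KRT5 lower (-1.17) among 7 tested (1 and 1 adjusted over the list alone; adjusted p = 0.913), and the call of KRT5, at 0.704 CPM after heat, was lost without unheated replicate 2 (adjusted p = 0.144), heat-shocked control replicate 1 (0.0776) or replicate 2 (0.0728), and with the DESeq2 Wald test (0.146). Blood cell markers had 2 tested members and no list test, with LCP1 at 0.10 and HBA2 at 3.69 ± 3.7 CPM after heat against 0 before (adjusted p = 0.189). HBA2 was called with the DESeq2 Wald test (adjusted p = 7.06e-04), in the fit without robust estimation (4.90e-05) and without heat-shocked control replicate 1 (3.19e-05) or replicate 2 (0.00163).

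Over all 17290 genes, heat shock raised 3559 and lowered 4033 at an edgeR adjusted p under 0.05, and 1006 and 606 of these changed at least 2-fold. With library size alone as the scaling the split was 2932 higher and 5092 lower, so that 36.5% rather than 46.9% of the called genes were higher. With the DESeq2 Wald test 2514 genes were lower, of which 378 at least 2-fold.

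Among protein-coding genes of at least 5 CPM on average, SAA1 had the largest fall in the knockdown. SAA1, an acute-phase protein, fell from 13.8 ± 1.99 to 0.35 ± 0.102 CPM (SD, n = 2, log2 fold change -5.27 ± 0.26 SE, adjusted p = 4.34e-14). TXNIP, which binds thioredoxin, fell by 3.70 on the log2 scale, the chemokine CXCL8 by 3.62, MMP9, a secreted gelatinase, by 3.44 and the apoptosis inhibitor BIRC3 by 3.21. TCIM, IFI44 and CTSS, a lysosomal protease, made up the rest of the 8 largest falls at that level. ACTBL2, an actin family gene, rose 19.9-fold (1.06 ± 0.524 to 21.5 ± 1.66 CPM), the granin SCG2 17.9-fold, the growth factor AREG 11.3-fold, LAMA3, a laminin chain, 10.4-fold, IGFL2 8.52-fold, SCN3B 8.49-fold, TMEM198 8.35-fold and KLC3 7.69-fold.

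NF-kB targets were lower in the knockdown, 12 of 15 against 1 higher (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.76, CCL2 at -2.46 and NFKBIA at -1.52 (camera adjusted p = 2.99e-12, but adjusted p = 0.077 with an estimated correlation). Interferon-stimulated genes were lower in 19 of 26 and higher in 1 (19 and 1 adjusted over the list alone), with a median of -1.09, IFIT3 at -2.88 and STAT2 at -0.47 (camera adjusted p = 1.31e-04, but adjusted p = 0.106 with an estimated correlation). Immediate early genes were higher in 19 of 26 and lower in 3 (19 and 3 adjusted over the list alone), with NR4A1 up 2.9-fold, FOS 2.17-fold and ATF3 3.48-fold (camera adjusted p = 2.04e-08, but adjusted p = 0.077 with an estimated correlation). Targets of p53 were higher in 15 of 26 and lower in 4 (15 and 5 adjusted over the list alone), with FDXR at 1.29, TP53I3 at 1.11, POLH up 2.14-fold and MDM2 at 0.83 (camera adjusted p = 2.33e-05, but adjusted p = 0.106 with an estimated correlation). Of 27 G2/M genes 20 were higher and 3 lower (20 and 3 adjusted over the list alone), with CENPE at 0.86 and CCNA2 at 0.78. The kinase AURKA fell by 1.53 (list camera adjusted p = 8.27e-06, but adjusted p = 0.578 with an estimated correlation). Of 12 histone genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with H2BC11 up 3.52-fold and H2AC6 at -0.96 (camera adjusted p = 0.0157, but adjusted p = 0.657 with an estimated correlation). That call was lost at the preset value without heat-shocked control replicate 2 (adjusted p = 0.0809) or knockdown replicate 2 (0.0868).

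Chaperones fell by small amounts in the knockdown. Of 43 tested 27 fell and 6 rose (28 and 7 adjusted over the list alone), with a median log2 fold change of -0.16, HSPH1 at -0.59 and CRYAB, a small heat shock protein, at -0.50 (camera adjusted p = 0.00357, but adjusted p = 0.578 with an estimated correlation). Against unheated controls 35 of the 43 were higher in the knockdown and 4 lower (36 and 4 adjusted over the list alone), with a median of 1.58 (camera adjusted p = 6.58e-104, and adjusted p = 0.031 with an estimated correlation). In the list of heat shock transcription factors and other HSF1 targets 12 of 19 genes were higher, HSF1 among them, and 2 lower (13 and 2 adjusted over the list alone). ARC was at 0.91, IER5 at 0.64 and SLC5A3 at -0.68 (list camera adjusted p = 0.00675, but adjusted p = 0.203 with an estimated correlation).

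End joining genes again moved both ways in the knockdown, with 7 of 22 lower, 4 higher and 11 not passing (4 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.523). The fry rotation test called the list lower (fry adjusted p = 0.0375). TP53BP1 (ENSG00000067369, chromosome 15, 43403061 to 43510640), which favours end joining over resection, fell from 128 ± 0.0869 to 60.8 ± 1.91 CPM (log2 fold change -1.07 ± 0.05, adjusted p = 6.54e-14). APLF fell by 0.64, DCLRE1C by 0.47, NHEJ1 by 0.41, and XRCC5 and APTX by 0.24 each. SHLD2 rose by 0.60, PAXX by 0.46, POLL by 0.38 and MAD2L2 by 0.30. PRKDC was at -0.01 (adjusted p = 0.854), XRCC6 at -0.02 (0.715), LIG4 at -0.01 (0.943) and XRCC4 at 0.01 (0.947). Thus NHEJ1, DCLRE1C and APTX were higher with heat and lower with the knockdown, and SHLD2 and PAXX the reverse. The call of NHEJ1 was lost without knockdown replicate 1 (log2 fold change -0.26, adjusted p = 0.138) and with the DESeq2 Wald test (adjusted p = 0.0713), and that of APLF without knockdown replicate 2 (adjusted p = 0.165) and with the DESeq2 Wald test (0.0909).

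**Figure D2:**
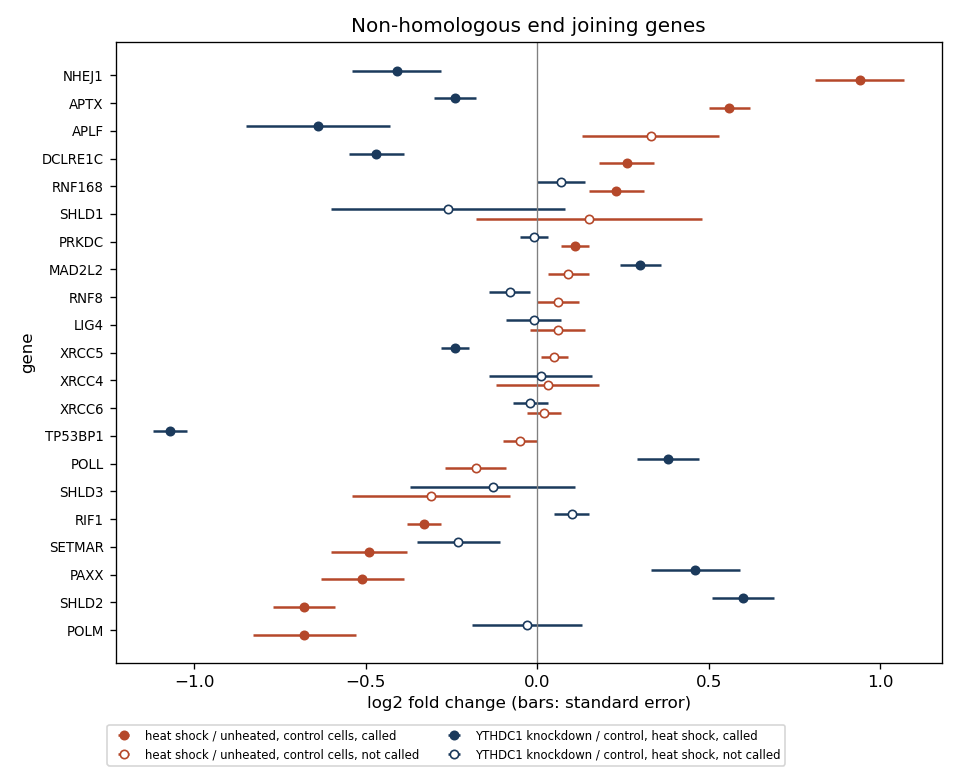
Log2 fold change of the tested end joining genes reported here (x axis, bars are SE, 2 libraries per group) in heat shock and in the knockdown, with filled points at an adjusted p under 0.05. NHEJ1 is at 0.94 in heat shock and -0.41 in the knockdown, and TP53BP1 at -0.05 and -1.07.

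Other repair genes were mixed in the knockdown. Homologous recombination had 8 of 30 higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.86), with BRCA2 up 1.99-fold and FANCI at -0.82. Base excision repair had 8 of 21 higher and 5 lower (8 and 5 adjusted over the list alone; adjusted p = 0.86), with TDG at 0.91 and PARP1 at -0.32. Nucleotide excision repair had 7 of 22 higher and 9 lower (7 and 10 adjusted over the list alone; adjusted p = 0.915), with XPC at 1.49 and CETN2 at -1.11. Mismatch repair had 2 of 8 higher and 3 lower (2 and 3 adjusted over the list alone; adjusted p = 0.142), with PCNA at -1.83. Damage signalling had 5 of 18 higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.793), with TIMELESS at -0.79 and WEE1, an inhibitory kinase of mitotic entry, at 0.63.

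Among the other lists in the knockdown, the unfolded protein response had 9 of 24 higher and 9 lower (10 and 9 adjusted over the list alone; adjusted p = 0.86), and its median of 0.09 differed in sign from its mean of -0.05. CALR, a calcium-binding chaperone of the endoplasmic reticulum, fell from 1806 ± 4.15 to 382 ± 5.11 CPM and PPP1R15A rose 2.7-fold. Ribosomal protein genes had 12 of 75 higher and 14 lower (10 and 14 adjusted over the list alone; adjusted p = 0.389), and 72 of the 75 lay within 0.5 of no change. RPL31 and RPL8 fell by 1.96 and 1.92. Splicing factors had 6 of 28 higher and 8 lower (6 and 8 adjusted over the list alone; adjusted p = 0.86), with TRA2B at -0.58. Of 22 m6A factors 3 were higher and 10 lower (4 and 11 adjusted over the list alone; adjusted p = 0.163), with the demethylase ALKBH5 at -0.68, YTHDF3 at -0.56 and RBM15B at 0.78. G1/S genes had 5 of 25 higher and 9 lower (5 and 9 adjusted over the list alone; adjusted p = 0.363), with UHRF1 at -1.16 and RRM2, a subunit of ribonucleotide reductase, at 1.06. Cholesterol synthesis had 11 of 22 higher and 6 lower (12 and 6 adjusted over the list alone; adjusted p = 0.26), with INSIG1 at 1.13 and SQLE at -1.04. Mitochondrial messenger RNAs had 2 of 13 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.915), with MT-ND5 at 0.42.

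Markers of other cell types also moved in the knockdown. Of 7 epithelial markers 5 rose (5 higher and 1 lower adjusted over the list alone), with EPCAM going from 5.44 ± 1.11 to 20.3 ± 0.386 CPM, KRT14 from 3.08 ± 0.00393 to 11.1 ± 1.77 CPM and CDH1, E-cadherin, from 1.22 ± 0.202 to 4.41 ± 0.529 CPM (camera adjusted p = 0.0557, and adjusted p = 0.38 with an estimated correlation). At the preset correlation the list passed without unheated replicate 1 (adjusted p = 0.0356), unheated replicate 2 (0.0357) or heat-shocked control replicate 2 (0.0499). Matrix genes had 11 of 26 higher and 8 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.389, adjusted p = 0.919 with an estimated correlation, and 0.00639 at the preset value without knockdown replicate 2), with ACTA2, smooth muscle actin, up 5.68-fold. Of 2 tested blood cell markers 1 was lower (1 adjusted over the list alone), LCP1, an actin-bundling protein of leukocytes, which fell by 1.99.

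**Figure D3:**
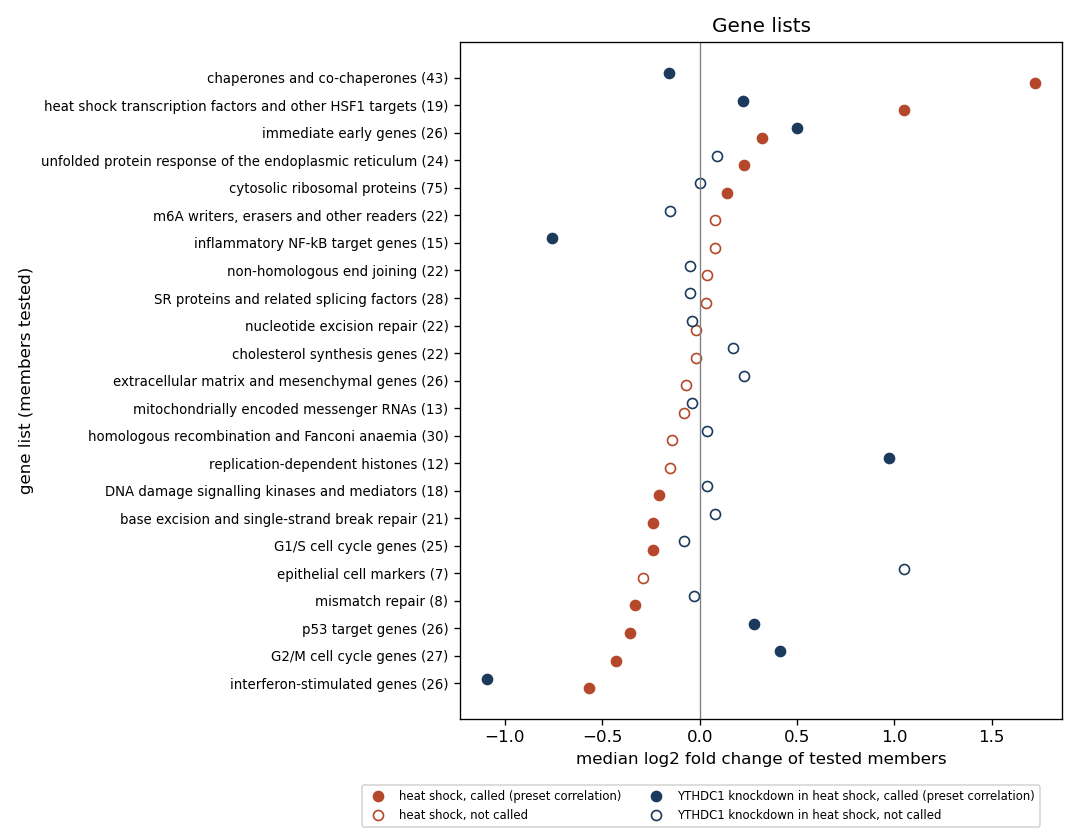
Median log2 fold change of the tested members of each gene list (x axis) in heat shock and in the knockdown, with filled points where camera at the preset correlation gave an adjusted p under 0.05. Chaperones are at 1.72 in heat shock and -0.16 in the knockdown, and p53 targets at -0.36 and 0.28. With an estimated correlation 3 of the 12 heat shock calls and 0 of the 8 knockdown calls held.

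Over all genes the knockdown raised 4729 and lowered 4696, with 1058 and 1139 changed at least 2-fold. Unheated knockdown cells were not analysed here, so these values do not separate an effect of the knockdown in heat from one without heat.

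Genes changed by both heat shock and the knockdown more often went opposite ways than the same way. Of 4689 genes called in both, 1453 were higher with heat and lower with the knockdown and 1614 the reverse, together 3067 (65.4%), while 699 rose in both and 923 fell in both. Those higher with heat and lower with the knockdown were led, by the sum of both absolute log2 fold changes among genes of at least 5 CPM on average, by PNLDC1 (6.48 and -0.89), DNAJA4 (5.88 and -0.16), PLPPR5 (5.38 and -0.58), TXNIP (1.76 and -3.70) and the kinase HUNK (3.89 and -1.47). Those with the reverse pattern included CHST14 (-1.55 and 2.76), MMP24 (-1.08 and 2.78), RAB11FIP4 (-1.47, then 4.61-fold higher), FJX1 (-2.46 and 1.37) and SPATA2L (-1.98 and 1.54). Of the 1006 genes that rose at least 2-fold with heat, 371 were lower and 126 higher in the knockdown (median log2 fold change -0.30), and of the 606 that fell at least 2-fold, 223 were higher and 63 lower (median 0.36).

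Both comparisons used the same heat-shocked control libraries, which alone produces opposite changes. In 50 simulations of unchanged groups the median number of opposite genes was 1 and the highest 5. With no gene changed almost none is called, so that number is no benchmark for the 3067 observed. Independent lists of the observed sizes would share 967 genes higher then lower and 1103 lower then higher. Across genes, which are not independent replicates, the fold changes correlated at -0.188 (simulated median -0.524), with a covariance of -0.109 against a simulated -0.0284, a difference of -0.0805. The spread of the heat-shocked control replicates gives a covariance of -0.0467, lower than the simulated value. Splitting the controls would leave 1 library on each side, so they were not split, and part of the excess may come from the shared libraries. The DESeq2 Wald test gave 1840 opposite genes.

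Heat-shocked knockdown cells against unheated controls, which differ in both heat and YTHDC1, had 5372 genes higher and 5384 lower, with 1634 and 1554 changed at least 2-fold. Immediate early genes were higher in 20 of 26 and lower in 6 (20 and 6 adjusted over the list alone; camera adjusted p = 5.77e-12, and adjusted p = 0.031 with an estimated correlation), and interferon-stimulated genes were lower in 18 of 26 and higher in 3 (18 and 3 adjusted over the list alone; camera adjusted p = 8.88e-07, and adjusted p = 0.0464 with an estimated correlation).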

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

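The alternatives were chosen before the data were examined, and 0 were added later. YTHDC1 stayed lower and past the threshold under every alternative run, with log2 fold changes between -1.17 and -1.11 when each library was left out. Gene counts moved by less than 1.5 times under DESeq2 size factors, upper-quartile scaling, library size alone, no filter, limma voom, fits of 2 groups, the fit without robust estimation and an adjusted p under 0.01, and when any library was left out. The stricter filter, which tests fewer genes, left 447 higher and 251 lower at least 2-fold in heat shock, 470 and 535 in the knockdown, and 774 and 787 in heat-shocked knockdown against unheated cells. With the DESeq2 Wald test 2514 genes were lower in heat shock, 378 of them at least 2-fold, and 1840 changed in opposite directions, and the cause was not tested. Asking for at least 2-fold in both comparisons left 281 opposite genes, by construction. With camera's estimated correlation 3 lists were called in heat shock and 0 in the knockdown. Camera at the preset correlation called 12 and 8, and fry, which asks another question, 18 and 13. In heat shock fry added homologous recombination, nucleotide excision repair and matrix genes lower. It added splicing factors, cholesterol synthesis and NF-kB targets higher (fry adjusted p from 0.00177 to 0.0354 over these lists). In the knockdown it added end joining, mismatch repair and m6A factors lower, and cholesterol synthesis and epithelial markers higher (7.45e-05 to 0.0375).

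Same-numbered replicates did not deviate together (correlations of -0.0094, -0.0230 and 0.0140 between groups). The labels do not say that a number marks a shared culture or day. Counting noise can pull such correlations to 0 even where cultures were shared, so pairing is not excluded. With a replicate block 3528 genes were higher and 3966 lower in heat shock, 4697 and 4675 in the knockdown, 12 and 8 lists were called, and 3034 genes were opposite, and HBA2 passed in heat shock (adjusted p = 1.78e-09). Over 257 named gene results, 4302 of 4364 values under the alternatives stayed on their side of the threshold, 44 lost the call and 18 gained it. Among values past the threshold in the main fit or the alternative, 0 reversed. Direction was not compared for those past it in neither. Many of these genes were named for a large change or a small adjusted p, which favours stable calls. Leaving out each library in turn gave 2326 to 3208 opposite genes. Leaving a library out leaves its group with 1, which is assumed to vary like the others. Depth limits genes under 5 CPM.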

Other observations

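All tests here were chosen after the results were seen, as were the genes named here outside the rule. The exact intervals, Fisher's exact p and permutation p below count genes as independent, which they are not. They do not measure the spread between libraries.

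Of 616 pseudogenes tested, 95 rose and 24 fell with heat (median log2 fold change 0.17), and 31 rose and 99 fell in the knockdown (median -0.15), where reads shared with parent genes leave single values uncertain. Of 618 protein-coding genes spanning over 300 kb 11.2% fell with heat and 38.3% rose in the knockdown, and of 2625 spanning under 10 kb 29.8% and 28.2%, with no test of the difference. The nuclear long noncoding RNAs NEAT1, the scaffold of paraspeckles, and MIAT were 2.84-fold and 2.74-fold lower in the knockdown (edgeR adjusted p = 2.54e-17 and 0.0211), MIAT with an SD of 38.3 CPM around 111 CPM.

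Of 2623 genes near silence before heating, under 2 CPM, 394 rose and 150 fell at least 2-fold. Without the low-count filter 495 rose and 173 fell (2.86 to 1), so the excess of rises was also present without it. That test cannot decide for or against the filter, because genes picked for a low unheated level have little room to be called 2-fold lower. A first test, on genes with unheated counts, removed rises by construction and was replaced. The choice of genes by a low unheated level stays open. Against the 394 rises, 244 genes fell to under 2 CPM (61.8% rises, exact interval 57.9 to 65.5%). Over all 17290 genes 1006 rose and 606 fell at least 2-fold, a similar split. Of the 394, 86 (21.8%, exact interval 17.8 to 26.2%) had a gene of at least 10 CPM ending within 10 kb upstream on their strand, against 9.52% of those that changed by less (odds ratio against all other near-silent genes 2.73, 2.04 to 3.63, Fisher's exact p = 2.77e-11, two-sided). A gene-dense neighbourhood is argued against, since the odds ratio for an expressed gene starting downstream was 1.07 (0.645 to 1.71). PNLDC1 lies 1026 bp beyond MRPL18 (1.73 with heat) and PTH2R 946 bp beyond PIKFYVE (-0.14), and the upstream genes of the other 6 of the 8 largest such rises were between -0.03 and 0.58; transcription running on from upstream stays a candidate source of some of these counts, as do own promoters, and the strand setting is uncertain.

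Of the 4696 genes called lower in the knockdown, 901 fell further than YTHDC1. 35 of these were above 100 CPM, among them the importin KPNB1 (-2.39), CALR (-2.24), STMN1 (-2.05), RPL31 (-1.96), RPL8 (-1.92) and the nucleolar NPM1 (-1.76). The median log2 fold change over all 2183 genes at that level was 0.00 (quartiles -0.24 and 0.23). TMM scaling itself holds this median near 0, so it cannot test scaling as a cause. With library size alone the knockdown's median over all tested genes was 0.01. Library size scaling fixes each library's total, so it could not show a general fall either. The 10 genes with the most counts held 7.62% and 8.14% in heat-shocked controls and 7.50% and 7.88% in the knockdown. Those shares argue against a few genes taking the counts. For the 9 genes with named pseudogene copies, those copies changed by -2.14% of the parents' loss, so the reads did not move there. Direct silencing of these 35 by the reagent cannot be told apart from dependence on YTHDC1, since the reagent sequence was not used here and there is 1 knockdown group.

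The opposite changes of heat and knockdown could come from the shared controls. The covariance of -0.109 was lower than the -0.0467 that the spread of the control replicates gives, by -0.0623. A deviation common to both heat-shocked control libraries would not show in that spread, so the shared controls stay open as a source. A proportionally weaker heat response in the knockdown cells is argued against for 922 of the 3067 opposite genes (30.1%, exact interval 28.4 to 31.7%), called past their unheated level on the side away from the heat change, and stays open for the other 2145. The 27 chaperones of at least 5 CPM that rose at least 2-fold lost a median 8.55% of their log2 fold change with heat. The other 359 such genes lost 12.5%, a difference of 3.96 points (permutation p = 0.6). These are shares of the log2 change, and the share of the level lost is not given by them. A first version set 38 chaperones that rose against 41 p53 and G2/M genes that fell (62.6 points, permutation p = 2.8e-04) and was replaced, because those lists had been picked for their reversal. A knockdown effect present without heat cannot be told apart, with 0 unheated knockdown libraries in the table.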
